A study of Homo sapiens with 8 samples.

How the data were processed

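RNA was measured in 8 libraries of IMR90 human lung fibroblasts, 2 for each combination of vector (MYOD or EMPTY) and medium (GM or DM), prepared per the labels' protocols with TRIzol and a TruSeq Stranded mRNA kit. The cells were at passage 21 to 28 per the labels. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which could be technical. Groups were taken from the sample labels alone. The replicate numbers 1 and 2 recur in every group, and nothing in the labels says that a shared number marks a shared culture or day. The deposited count files of the 4 libraries numbered 1 carry lane designations in their names and those numbered 2 do not, so the numbers could mark separate sequencing runs; the labels give no batch.

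The deposited count files hold whole read counts per Ensembl gene on hg19, made by the authors with HTSeq per the read-me file beside them. The submitters' processing notes also name FastQC, Bowtie2 2.0.5, MACS2 2.1.1.20160309 and DESeq2, and the builds hg19 and GRCh37. The aligner used for the RNA reads, the annotation release and the strand setting of the counting are not given in the sources used here. The kit marks strand, but with the counting setting unknown, reads of overlapping and antisense genes cannot be assigned with certainty. Reads of near-identical gene copies are uncertain too, because such copies can share reads. Reads on human MYOD1 can come from the mouse transgene or the endogenous gene, which these counts do not separate.

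The authors' deposited tables of 3 comparisons hold log2 fold changes computed by the authors with DESeq2, per the file headers and the read-me file. Their p-values, raw and adjusted, come from the same authors' deposited tables. These tables list HTSeq's classes of reads in no gene and of ambiguous reads as features. The score per MYOD region is the authors', as deposited in a list of regions common to MYOD cells in both media; how it was computed and whether libraries were pooled is not given in the sources used here. The Wald statistic, standard error and mean columns of the authors' tables were not used here.

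Each count file had 63677 genes and 5 HTSeq classes that are not genes. These classes were left out of library sizes and tests. Reads in no annotated gene made up 10.4% and 7.09% of the files in EMPTY GM, 8.99% and 7.93% in MYOD GM, 10.2% and 10.6% in EMPTY DM, and 12.4% and 12.5% in MYOD DM. Ambiguous reads made up 1.97% to 2.43%, and the other 3 classes held 0 reads. Symbols were matched to 39699 Ensembl identifiers through a table of gene names. The 37 genes of the mitochondrial genome had 0 reads in every file.

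Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passed edgeR's own expression filter, which left 22272, and libraries were scaled by TMM factors. A quasi-likelihood model with 1 mean per group was fitted to all 8 libraries, which share an estimate of the spread on 4 residual degrees of freedom, with a common biological coefficient of variation of 0.276. The contrasts were MYOD against EMPTY in each medium, DM against GM for each vector, and the difference of the MYOD effect between the media. P-values were adjusted by the Benjamini-Hochberg method over genes within a contrast, and genes with an adjusted p under 0.05 are said to have risen or fallen. Every adjusted p printed for a gene is edgeR's unless another tool is named. Values after ± are the SE of a log2 difference, or the SD over the 2 libraries of a group in CPM, which are counts scaled by effective library size. The SE was taken as the log2 difference divided by the root of the F statistic. It rests on the shared spread, although the growth medium pairs spread more than the differentiation medium pairs.

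A total of 22 gene lists was written before the data were examined, as were the groups, tests, other settings to be tried and the rule for naming genes. Of 507 list entries 502 matched a gene, 3 were second names of a listed gene and 2 (ACACA and NEFL) matched none; 466 genes were measured. Some genes stand for more than 1 process, so a list's name describes why its genes were collected, not what each does. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over 110 tests (22 lists in 5 contrasts). Beside this, camera with an estimated correlation and fry were run. Of 39 list tests called with the preset value, the 3 of the sarcomere list in differentiation medium, in the move of MYOD cells and in the difference between media held with an estimated correlation. Calls were lost also where the estimate was under the preset value. Examples are cell cycle exit in the move of EMPTY cells (estimate 0.0036) and the epithelial, endothelial and blood list in the move of MYOD cells (−0.080), both at adjusted p = 0.11. A call lost with an estimated correlation therefore does not show that correlation between genes accounts for it. The fry test, which asks only whether members move one way on balance, called 48. Counts given as adjusted over the list alone repeat the adjustment over the measured members of that list. In 11 of the 110 tests a list's median, its mean and the direction of its test differed in sign, and 0 of these were called.

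Genes are named by a fixed rule. Part 1 takes the 8 largest positive and the 8 largest negative log2 differences in each contrast among protein-coding genes that have a symbol and an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and every library of 1 group above the other; for the difference of effects, both replicate numbers had to show the same sign. Part 2 takes up to 4 list members with the smallest adjusted p in each contrast and any list member named as not having passed. Part 3 is MYOD1 in every library, and part 4 the 5 regions of highest score. A few genes that the rule takes are not reported here. Members outside this rule that complete a count of 5 or fewer are named without values and said to have been chosen after their values were seen.

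Where a group held 0 reads of a gene, the change is given as a bound against 3 reads over that group, and with 1 to 3 reads as a ratio of reads with an exact 95% interval. Such intervals and bounds cover counting error only, since reads are not independent molecules. The libraries of each pair were compared on their counts: chi-square per degree of freedom was 177 in EMPTY GM, 105 in MYOD GM, 39.9 in EMPTY DM and 28.5 in MYOD DM, so none was a repeat deposit of another. For the comparison of long and short transcripts, 55 genes with a long coding sequence and 58 genes for small proteins were collected by name, of which 55 and 56 were measured. Those lists were written after the spread of the growth medium pairs was seen.

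The fit was checked on simulated counts of 21587 genes with 200 changed. For MYOD in growth medium it recovered 98% of genes changed 8-fold, 80% of those changed 4-fold, 2% at 2-fold and 0% at 1.5-fold, and 9.09% of its calls were false. For the move of MYOD cells the shares were 98%, 76%, 8% and 0%, with 13.3% false, and for the difference of effects 90%, 16%, 0% and 0%, with 13.1% false. In the contrasts with no simulated change it called 0 genes. Of 200 random lists in the simulated growth medium comparison 2% had a camera p under 0.05. The simulated libraries were drawn independently, with the same spread of a gene in every group. The real growth medium pairs spread more than the differentiation medium pairs and deviated together. The simulated shares therefore need not hold for the real counts.

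The other settings fixed beforehand were DESeq2 1.42.0, RLE factors, library size as the only scaling, no filter on low counts, a filter at 1 CPM in 2 libraries, the replicate number as a block, a fit of only the libraries compared, and each library left out in turn. Chosen after seeing the data were a block of the replicate number within each medium, and fits without the growth medium libraries numbered 1 or without those numbered 2. Which genes lie near the MYOD regions, and whether E-box sequences occur in the regions, was not analysed here, because no hg19 sequence or gene positions were used. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made the tables and figures.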

Results

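RNA sequencing was carried out on IMR90 cells, a line of human lung fibroblasts, that carried either a TET-inducible vector for mouse MYOD or the EMPTY control vector. MYOD is a basic helix-loop-helix transcription factor that can direct fibroblasts into the skeletal muscle lineage. Doxycycline at 200 ng/ml was given for 24 h in EMEM with 10% FBS, the growth medium (GM). For the differentiation medium (DM), the same 24 h were followed by 3 days in EMEM with 2% HS and 1% ITS, so that medium and time differ together between the media. The 8 libraries formed 4 groups of 2: EMPTY GM, MYOD GM, EMPTY DM and MYOD DM. Reads on annotated genes numbered 31935089 and 33831242 in EMPTY GM and 38150957 and 30249593 in MYOD GM. They numbered 37916041 and 44698199 in EMPTY DM and 39452995 and 26514754 in MYOD DM. A list of 27777 chromosomal regions from MYOD chromatin immunoprecipitation was deposited beside the RNA data. The comparisons ask which genes MYOD changes in each medium and which change when each kind of cell moves to differentiation medium.

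The vector separated the libraries on the first principal component and the medium on the second. The growth medium pairs lay farther apart than the differentiation medium pairs. The first principal component held 54.3% of the variance and the second 27.5%. On the first, the MYOD GM libraries stood at 39.1 and 16.8 and the MYOD DM libraries at 143.9 and 130.8, so the media of MYOD cells lay apart there too. On the second, EMPTY GM library 1 stood at −14.5, EMPTY GM library 2 at 80.8 and the EMPTY DM libraries at −79.9 and −72.9. EMPTY GM library 1 thus lay nearer to the EMPTY DM libraries than to its partner. The SD over genes of the log2 differences between the libraries of a pair was divided by the root of 2 to give a spread per library. That spread was 0.65 in EMPTY GM, 0.54 in MYOD GM, and 0.31 in both EMPTY DM and MYOD DM. In EMPTY GM 5390 of 22272 genes differed over 2-fold between the pair, against 3164 in MYOD GM, 926 in EMPTY DM and 945 in MYOD DM. Genes with a long coding sequence and genes for small proteins were set against each other within each library. The median log2 level of the long genes minus that of the small ones was −0.26 and −1.62 in EMPTY GM, 0.35 and −1.19 in MYOD GM, 1.04 and 0.69 in EMPTY DM, and 0.78 and 0.63 in MYOD DM.

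**Figure D1:**
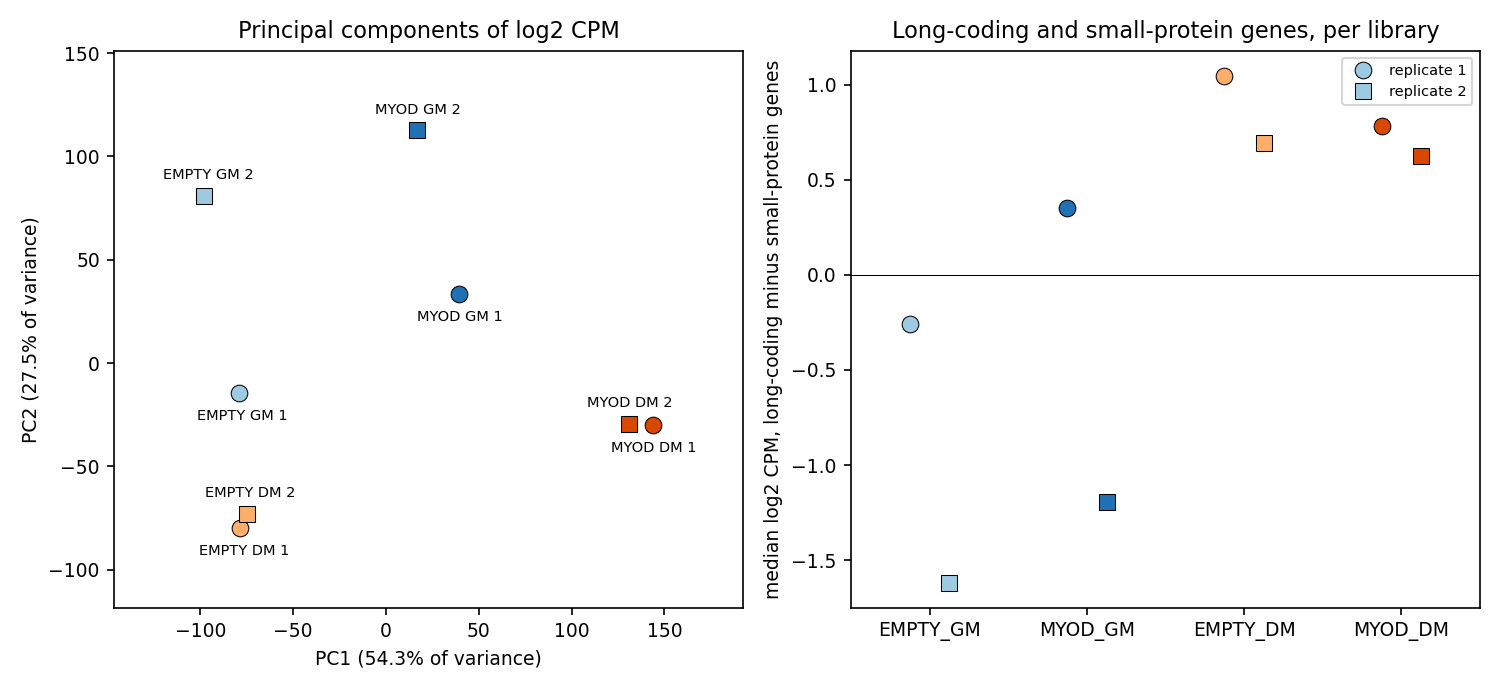
Left, the 8 libraries on the first and second principal components of log2 CPM, with 54.3% and 27.5% of the variance on the axes. Right, the median log2 CPM of 55 genes with a long coding sequence minus that of 56 genes for small proteins, 1 point per library, which ran from −1.62 in EMPTY GM library 2 to 1.04 in EMPTY DM library 1.

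MYOD1 (ENSG00000129152) was checked first, because reads of the mouse transgene can be counted on the human gene; transgene and endogenous reads were not separated. It reached 281 and 261 CPM (counts scaled by effective library size, as edgeR does) in the MYOD GM libraries and 106 and 99.6 CPM in the MYOD DM libraries. In the control libraries it stood at 0.0577 and 0.759 CPM in EMPTY GM and at 0.226 and 0.472 CPM in EMPTY DM. The log2 difference from the control was 9.39 ± 0.80 (SE) in growth medium and 8.17 ± 0.76 in differentiation medium, with edgeR adjusted p = 4.5e-04 and 2.6e-04. MYOD1 was thus high in all 4 MYOD libraries, and each EMPTY library stayed below 1 CPM. Within the MYOD cells the level in differentiation medium differed from that in growth medium by −1.40 ± 0.54, adjusted p = 0.14, which did not pass the test. In the authors' deposited table MYOD1 differed by −1.35 with an adjusted p = 4.4e-06, which passed.

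**Figure D2:**
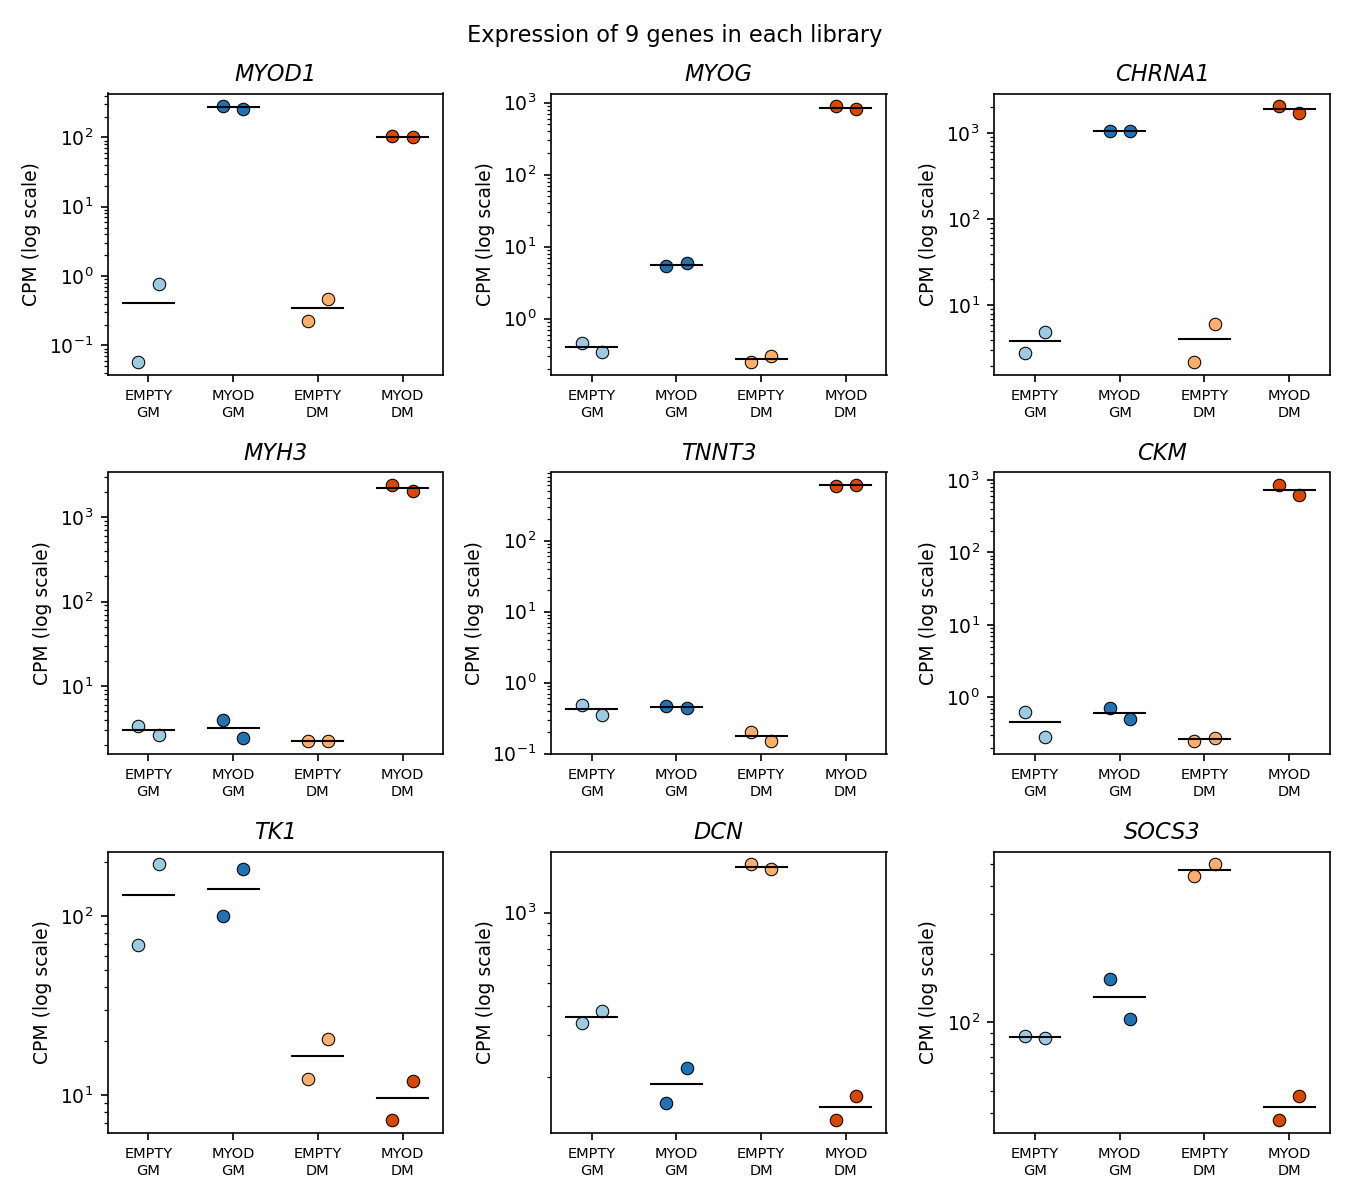
CPM on a log axis for 9 genes (MYOD1, MYOG, CHRNA1, MYH3, TNNT3, CKM, TK1, DCN and SOCS3) in the 4 groups. Dots are libraries (2 per group) and bars are group means; TNNT3 and CKM lay below 1 CPM in every group except MYOD DM, where their means were 599.6 and 729.9 CPM.

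In growth medium, 15 of 23 genes of calcium handling and the neuromuscular junction, 13 of 23 of fusion and the muscle membrane and 21 of 39 of the sarcomere rose with 24 h of MYOD induction. These lists were called by camera, but not with an estimated correlation (adjusted p = 0.089, 0.098 and 0.074). CHRNA1 (ENSG00000138435), the alpha subunit of the muscle acetylcholine receptor, rose from 3.83 ± 1.51 to 1051 ± 8.34 CPM (mean ± SD, n = 2; log2 8.10 ± 0.60, adjusted p = 2.5e-04). Its delta subunit CHRND rose from 0.802 ± 0.0729 to 149.5 ± 0.933 CPM (log2 7.54 ± 0.38, adjusted p = 7.5e-05). DYSF, a protein of muscle membrane repair, rose by 7.39 ± 0.38, adjusted p = 7.5e-05, and MYMX, a micropeptide of myoblast fusion, by 7.45 ± 0.58, adjusted p = 3.3e-04. MYOG (ENSG00000122180), the myogenin gene, rose by 3.78 ± 0.27 and reached 5.64 ± 0.352 CPM. The others among the 8 largest rises by the naming rule, which asks for at least 10 CPM in the higher group, were SHD (8.25 ± 0.39), the sialyltransferase gene ST8SIA5 (7.86 ± 0.36) and UNC45B (7.30 ± 0.41), a myosin chaperone.

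By the same rule the largest falls in growth medium were in CYP1B1 (−3.93 ± 0.56, adjusted p = 0.0047), a cytochrome P450, and ANGPTL4 (−3.88 ± 0.72, adjusted p = 0.015), an inhibitor of lipoprotein lipase. F3, the tissue factor gene, went from 89.6 ± 5.13 to 11.3 ± 1.84 CPM (log2 −2.99 ± 0.43, adjusted p = 0.0052). IL27RA (−2.93 ± 0.38), IL2RB (−2.89 ± 0.38) and IL7R (−2.73 ± 0.47), which encode cytokine receptor chains, were also among these 8 falls. S100A3 (−2.94 ± 0.41) and PLEKHG4 (−2.73 ± 0.29) completed the 8.

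All 5 muscle lists were raised in growth medium. Of 39 measured sarcomere genes 21 rose and 18 did not pass, with 24 rising when adjusted over the list alone (camera adjusted p = 2.0e-29, and adjusted p = 0.074 with an estimated correlation). The embryonic actin gene ACTC1 rose from 18.0 ± 2.10 to 2283 ± 16.8 CPM, KLHL41 rose by 6.66 ± 0.36 and the slow troponin gene TNNI1 by 5.91 ± 0.36. Among 23 genes of calcium handling and the neuromuscular junction 15 rose, also when adjusted over the list alone (camera adjusted p = 4.2e-32, and adjusted p = 0.089 with an estimated correlation). Examples were DOK7 (7.25 ± 0.40), CHRNB1 (4.78 ± 0.28) and STAC3 (5.80 ± 0.38). For fusion and muscle membrane 13 of 23 rose, against 14 higher and 1 lower when adjusted over the list alone (camera adjusted p = 8.8e-24, and adjusted p = 0.098 with an estimated correlation). CAV3 (7.09 ± 0.36), SGCA (6.45 ± 0.33) and CDH15 (7.05 ± 0.54) were among them. Of 20 genes of muscle energy metabolism 9 rose, against 11 higher and 1 lower over the list alone (camera adjusted p = 7.3e-06, and adjusted p = 0.20 with an estimated correlation). PGAM2 (5.23 ± 0.54) and ENO3 (2.96 ± 0.44) were among these. Of 11 myogenic regulators MYOD1, MYOG, MEF2D (1.79 ± 0.31) and MEF2C (1.58 ± 0.37) rose, and 7 did so over the list alone (camera adjusted p = 8.3e-07, and adjusted p = 0.11 with an estimated correlation).

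Fibroblast transcription factors and interferon response genes were lower with MYOD in growth medium. Of 28 fibroblast and lung mesenchyme factors 6 fell and 1 rose (9 and 1 when adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.25 with an estimated correlation). NFIB (−1.32 ± 0.22), NR2F1 (−1.44 ± 0.25), OSR1 (−2.01 ± 0.35) and TBX5 (−1.29 ± 0.24) were among those that fell. RUNX1 rose. Of 25 interferon response genes 9 fell and 1, HERC5, rose (10 and 2 over the list alone; camera adjusted p = 7.3e-04, and adjusted p = 0.28 with an estimated correlation). Among them the antiviral genes MX1 and OAS2 fell (−2.47 ± 0.37 and −2.81 ± 0.46), and OAS1, with 3 reads in MYOD GM, was lower by a factor of 26.7 (95% counting interval 8.80 to 132). Of 14 cartilage and bone markers 5 rose, also over the list alone (camera adjusted p = 0.0082, and adjusted p = 0.20 with an estimated correlation): RUNX2 (3.07 ± 0.40), ACAN (2.84 ± 0.39), COL2A1 (2.86 ± 0.47), SP7, higher by a factor of 54.8 (95% counting interval 9.45 to 2202), and ALPL. HERC5, RUNX1 and ALPL were chosen after their values were seen.

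The lists that follow did not pass as lists in growth medium. For cell cycle progression no member of 34 passed edgeR's adjusted test, 1 was higher at an unadjusted p under 0.05 and DESeq2 called 0 (camera adjusted p = 0.95); MCM2 differed by 0.55 ± 0.22, adjusted p = 0.21. Of 16 genes of cell cycle exit the inhibitors CDKN1C (5.40 ± 0.53) and CDKN1A (1.39 ± 0.27) and the cyclins CCND1 (1.25 ± 0.23) and CCND2 rose and CDKN2B (−1.38 ± 0.31) fell (camera adjusted p = 0.14; 6 higher and 3 lower over the list alone). Of 34 matrix genes THBS2 (1.65 ± 0.32) rose and PDGFRA (−2.51 ± 0.38) and LUM (−1.39 ± 0.32) fell (camera adjusted p = 0.26; 1 and 4 over the list alone). Of 19 myofibroblast genes ANKRD1 (4.12 ± 0.42) rose and 2 fell, among them CCN2 (−1.11 ± 0.25) (camera adjusted p = 0.42; 1 and 3). In the Notch and ID list the ligand DLL1 (6.95 ± 0.47), HEYL (4.18 ± 0.34), JAG2 (2.46 ± 0.40) and HEY1 rose and JAG1 (−2.04 ± 0.33) fell, out of 19 (camera adjusted p = 0.078; 5 and 2); as a list it passed, higher, in 5 of 13 alternatives. CCND2 and HEY1 were chosen after their values were seen.

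Single members of further lists passed in growth medium. The chromatin genes SMARCD3 (1.16 ± 0.23) and KAT2B (1.42 ± 0.30), of 30, rose, also over the list alone (camera adjusted p = 0.63). CCL2 (−1.84 ± 0.41) and NFKBIA (−1.26 ± 0.31), of 22 inflammatory genes, fell (camera adjusted p = 0.17; 4 lower and 1 higher over the list alone). DHCR7 (1.00 ± 0.25) rose and FADS2 (−1.49 ± 0.31) fell among 23 sterol and fatty acid genes, also over the list alone (camera adjusted p = 0.73). DUSP4 (3.93 ± 0.38) and KLF2 (1.29 ± 0.25) rose and IER3 (−1.66 ± 0.26) fell among 25 serum response genes, also over the list alone (camera adjusted p = 0.80). HMOX1 (1.80 ± 0.31) and HERPUD1 (0.99 ± 0.22) rose and TXNRD1 (−1.06 ± 0.26) fell among 19 stress genes (camera adjusted p = 0.26; 3 and 2 over the list alone). Of 11 cardiac markers MYBPC3 rose (camera adjusted p = 0.76; 3 higher and 2 lower over the list alone). Of 13 neuronal markers GAP43 (2.30 ± 0.44), SYT1 (1.63 ± 0.38) and SNAP91 rose (camera adjusted p = 0.17; 4 and 1). Of 7 adipocyte markers PLIN4 (3.49 ± 0.36) and CIDEC (4.12 ± 0.67) rose and PPARG (−2.15 ± 0.47) fell (camera adjusted p = 0.17; 4 and 2). MYBPC3 and SNAP91 had 1 read each in EMPTY GM, so their ratios were 45.2 (95% counting interval 7.72 to 1822) and 71.2 (95% counting interval 12.4 to 2848). No epithelial, endothelial or blood marker of 11 passed in edgeR; at an unadjusted p under 0.05, 1 was higher and 3 were lower, and DESeq2 called 2 lower, as did edgeR over the list alone (camera adjusted p = 0.69).

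Over all 22272 genes tested, edgeR's quasi-likelihood test called 1855 genes for MYOD in growth medium, 1396 higher and 459 lower, of which 1357 and 428 changed at least 2-fold. The count was 894 without MYOD GM library 1, 1182 and 1189 without MYOD DM library 1 or 2, and 3586 without both growth medium libraries numbered 2. With no filter on low counts it was 3026, and in a fit of the EMPTY GM and MYOD GM libraries alone 558.

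In differentiation medium 36 of 39 sarcomere genes were higher in MYOD cells than in EMPTY cells, and 21 of 34 matrix genes typical of fibroblasts were lower. With an estimated correlation the sarcomere call held (adjusted p = 0.018) and the matrix call did not (adjusted p = 0.28). TNNT3 (ENSG00000130595), the fast skeletal troponin T gene, went from 0.175 ± 0.0356 to 599.6 ± 3.46 CPM (mean ± SD, n = 2; log2 11.72 ± 0.34, adjusted p = 4.4e-06). MYOG went from 0.276 ± 0.0352 to 848 ± 60.0 CPM (log2 11.56 ± 0.33, adjusted p = 4.4e-06) and the muscle creatine kinase gene CKM (ENSG00000104879) from 0.265 ± 0.0200 to 729.9 ± 159 CPM (log2 11.41 ± 0.48, adjusted p = 7.2e-06). The fusion protein gene MYMK rose by 11.91 ± 0.90, adjusted p = 1.0e-04. DCN (ENSG00000011465), the decorin gene, stood at 1568 ± 55.6 CPM in EMPTY DM and 148 ± 25 CPM in MYOD DM (log2 −3.40 ± 0.27, adjusted p = 1.2e-04). In growth medium it stood at 339 and 380 CPM in EMPTY GM and at 155 and 217 CPM in MYOD GM.

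Several of the largest rises by the naming rule in differentiation medium started from few or no reads in the control. ADGRA1, an adhesion receptor gene, and PRKAG3, a subunit of AMP-activated kinase, had 0 reads in EMPTY DM and reached 28.2 ± 11.8 and 21.2 ± 0.745 CPM. Against a floor of 3 reads over the control group ADGRA1 was at least 776-fold higher. APOBEC2, with 2 control reads, was higher by a factor of 5220.4 (95% counting interval 1445 to 43114). The calcium channel gene CACNA1S, also with 2, was higher by 4149 (95% counting interval 1148 to 34267), and LMOD3, with 1, by 4144 (95% counting interval 743 to 163728). UNC45B rose by 11.68 ± 0.47, adjusted p = 6.8e-06. By the same rule, with its minimum of 10 CPM, the largest falls were in the scavenger receptor gene SCARA5 (−6.64 ± 0.56, adjusted p = 1.8e-04), complement factor I gene CFI (−6.48 ± 0.77, adjusted p = 7.7e-04), SLITRK6 (−6.47 ± 0.72), the prolactin receptor gene PRLR (−5.94 ± 0.63), ATP1B2 (−5.59 ± 0.48), OLR1 (−5.31 ± 0.31), GALNT15 (−5.28 ± 0.44) and ADAM33 (−5.23 ± 0.45).

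All 5 muscle lists were raised in differentiation medium, each in most of its members. Of 39 sarcomere genes 36 rose and 3 did not pass, with 37 rising over the list alone; this call held with an estimated correlation (camera adjusted p = 7.3e-117, and adjusted p = 0.018 with an estimated correlation). ACTC1 rose from 11 ± 1.53 to 18420.4 ± 5033 CPM, MYL11 by 11.52 ± 0.38 and SMPX by 11.38 ± 0.43; values of single actin genes and of neighbouring myosin genes are uncertain, because near-identical copies can share reads. Of 23 calcium handling and junction genes 20 rose (21 higher and 1 lower over the list alone; camera adjusted p = 3.5e-58, and adjusted p = 0.074 with an estimated correlation). Among them were RYR1 (9.35 ± 0.34), HRC (9.95 ± 0.39) and the calcium pump gene ATP2A1 (6.02 ± 0.27). Of 23 fusion and membrane genes 19 rose and 1, KIRREL1, chosen after its values were seen, fell (21 and 1 over the list alone; camera adjusted p = 3.4e-27, and adjusted p = 0.089 with an estimated correlation). NCAM1 rose by 11.62 ± 0.69 and CAV3 by 9.89 ± 0.39. Of 20 energy genes 14 rose, also over the list alone (camera adjusted p = 2.3e-15, and adjusted p = 0.10 with an estimated correlation), with PGAM2 at 8.34 ± 0.61 and ENO3 at 6.54 ± 0.51. Of 11 regulators 7 rose (10 over the list alone; camera adjusted p = 1.3e-09, and adjusted p = 0.10 with an estimated correlation), including MEF2C (5.58 ± 0.44) and MEF2D (1.91 ± 0.31).

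Matrix, mesenchymal transcription factor and interferon lists were lower in MYOD DM than in EMPTY DM. On the move to differentiation medium the median log2 change of the matrix list was 0.92 in EMPTY cells and −0.25 in MYOD cells. Much of the gap in that list was thus a rise in the control. Of 34 matrix genes 21 fell and 4 rose (22 and 4 over the list alone; camera adjusted p = 4.1e-06, and adjusted p = 0.28 with an estimated correlation). TGFBI went from 3208 ± 74.4 to 382 ± 145 CPM and the collagenase gene MMP2 from 642 ± 0.388 to 103 ± 39.9 CPM. The rises were in MFAP5 (6.31 ± 0.57), THBS2, VCAN and S100A4. Of 28 transcription factors 15 fell and 13 did not pass (17 lower and 2 higher over the list alone; camera adjusted p = 5.9e-05, and adjusted p = 0.11 with an estimated correlation). Values were HOXA5 at −3.43 ± 0.25, OSR1 at −4.56 ± 0.40, TBX5 at −2.43 ± 0.25 and NR2F1 at −2.08 ± 0.26. Of 25 interferon genes 9 fell and 16 did not pass (11 over the list alone; camera adjusted p = 0.0014, and adjusted p = 0.30 with an estimated correlation). MX2 (−2.35 ± 0.32), OAS3 (−1.85 ± 0.29), IFIT1 (−2.58 ± 0.45) and IFIH1 (−2.03 ± 0.37) were among those that fell. THBS2, VCAN and S100A4 were chosen after their values were seen.

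Immediate-early and inflammatory genes split by member. Of 25 serum response genes 12 fell and 8 rose (13 and 8 over the list alone; camera adjusted p = 0.079): JUNB (−3.58 ± 0.30), KLF4 (−4.55 ± 0.40) and IER2 (−2.40 ± 0.25) fell and DUSP4 (5.57 ± 0.37) rose. Of 22 inflammatory genes 7 fell, such as ICAM1 (−2.50 ± 0.25), NFKBIA (−2.35 ± 0.32) and IL6 (−2.51 ± 0.42), and IL11 (2.82 ± 0.46) and MMP1 rose (camera adjusted p = 0.055; the same numbers over the list alone). Of 19 stress genes 6 fell (7 over the list alone; camera adjusted p = 0.055), including TRIB3 (−1.35 ± 0.31), TXNRD1 (−0.98 ± 0.26) and the near-identical pair HSPA1A (−1.30 ± 0.31) and HSPA1B (−1.40 ± 0.29), whose reads cannot be told apart with certainty. In the Notch and ID list HEYL (6.43 ± 0.37), DLL1 (5.96 ± 0.41), HEY1 (4.22 ± 0.40), NOTCH1, JAG2 and LFNG rose, and ID1, ID2 (−1.56 ± 0.21), ID3, ID4 and TCF3 fell (camera adjusted p = 0.42; 6 and 6 over the list alone). The ID proteins bind and inhibit partners of MYOD. Over 13 alternatives the serum response list passed in 7, the stress list in 9 and the inflammatory list in 4, always lower with MYOD. No cell cycle progression gene of 34 passed in edgeR's fit of all libraries. At an unadjusted p under 0.05, 3 were lower, and DESeq2 called 0 (camera adjusted p = 0.17). The cell cycle progression list passed, lower, in 3 of 13 alternatives. Among 16 exit genes CDKN1A (2.03 ± 0.27), CDKN1C (5.42 ± 0.52), CCND2 and CCND3 rose and GADD45B (−3.02 ± 0.32), BTG2 (−1.84 ± 0.35), CDKN1B and RBL1 fell, also over the list alone (camera adjusted p = 0.95). MMP1, NOTCH1, JAG2, LFNG, ID1, ID3, ID4, TCF3, CCND2, CCND3, CDKN1B and RBL1 were chosen after their values were seen.

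Myofibroblast, chromatin and sterol genes went in both directions in differentiation medium. Of 19 myofibroblast and smooth muscle genes ANKRD1 (8.23 ± 0.50), ACTA2, TPM1 and SMTN rose, and CCN2 (−1.89 ± 0.25), CCN1 (−1.59 ± 0.24), MYH10 (−1.68 ± 0.27), CNN1 and LMOD1 fell (camera adjusted p = 0.99; 5 and 5 over the list alone). The median log2 difference of that list was −0.66, whereas its mean of 0.24 and its test pointed up. Of 30 chromatin genes SMARCD3 (1.47 ± 0.23), HDAC9 (2.53 ± 0.55), RAD21 and LMNA rose and SMARCD2 (−1.33 ± 0.22), SMARCD1 (−0.85 ± 0.20) and SMARCA2 fell, also over the list alone (camera adjusted p = 0.83). Of 23 sterol genes 3 rose, among them FDFT1 (1.20 ± 0.24) and IDI1 (1.45 ± 0.33), and FADS2 (−1.60 ± 0.31) fell, also over the list alone (camera adjusted p = 0.26). ACTA2, TPM1, SMTN, CNN1, LMOD1, RAD21, LMNA and SMARCA2 were chosen after their values were seen.

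Markers of other cell types changed in part. The cardiac genes MYH6, NPPA and NKX2-5 had 0 reads in EMPTY DM and were at least 35.5-fold, 30.1-fold and 8.44-fold higher with MYOD, at 1.29, 1.09 and 0.307 CPM (camera adjusted p = 0.19; 3 of 11 rose, also over the list alone). Of 13 neuronal markers SNAP91 (4.39 ± 0.64), GAP43 (2.89 ± 0.43) and STMN2, with 1 control read and a ratio of 118 (95% counting interval 20.6 to 4699), rose and SNAP25 (−1.80 ± 0.47) fell (camera adjusted p = 0.62; 3 and 3 over the list alone). CD36 (4.73 ± 0.35), a fatty acid transporter gene, PLIN4 (2.01 ± 0.34) and CIDEC (3.03 ± 0.63) rose and FABP4 (−3.41 ± 0.56) and PPARG fell among 7 adipocyte markers (camera adjusted p = 0.43; 3 and 3). Of 14 cartilage and bone markers ACAN (5.94 ± 0.47), SP7 (6.90 ± 0.71), RUNX2 (2.55 ± 0.39) and COL2A1 rose and COL11A2 (−2.43 ± 0.36), SOX9, IBSP and MATN3 fell (camera adjusted p = 0.44; 6 and 4). KRT8 (−1.40 ± 0.24), KRT18 (−1.61 ± 0.38), the endothelial receptor gene TEK (−2.07 ± 0.35) and the leukocyte gene PTPRC (−4.01 ± 0.64) fell and VWF rose among 11 (camera adjusted p = 0.082; 1 and 6). PPARG, COL2A1, SOX9, IBSP, MATN3 and VWF were chosen after their values were seen.

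edgeR called 5898 genes for MYOD in differentiation medium, 2842 higher and 3056 lower, of which 2544 and 2665 changed at least 2-fold. Which direction held more genes depended on the scaling, with 3006 higher and 2879 lower by RLE factors and 2460 and 3610 with library size only. The count was 2795 and 3287 without EMPTY DM library 1 or 2, 2391 and 3214 without MYOD DM library 1 or 2, and 11302 and 11427 without the growth medium libraries numbered 1 or 2. In a fit of the differentiation medium libraries alone it was 11033. Reads outside annotated genes made up 12.4% and 12.5% of the MYOD DM files against 10.2% and 10.6% in EMPTY DM, and nuclear copies of mitochondrial genes held 4.78% and 5.52% of gene reads against 3.51% and 3.54%.

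The genes that MYOD changed in growth medium were largely among those it changed in differentiation medium. In both media 1099 genes were higher and 402 lower, 1501 in all, where lists of these sizes drawn independently would share 178.1 and 62.98. Those are not the numbers without a shared effect, because the same fit gave each gene's spread to both tests. Of the genes higher in growth medium 78.7% were also higher in differentiation medium, and of those lower 87.6% were also lower. The 2 comparisons share no library, and their log2 differences correlated across genes with Pearson's r of 0.72 and Spearman's rho of 0.60; genes are not independent replicates. CHRNA1, DYSF, CAV3, UNC45B, NR2F1, OSR1 and TBX5 were called the same way in both. Calls went opposite ways for 21 genes. The shared count was 939 and 923 without EMPTY DM library 1 or 2, 859 and 937 without MYOD DM library 1 or 2, 803 without MYOD GM library 1, and 2668 without the growth medium libraries numbered 2.

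Among genes that met the naming rule, the 8 with the largest gain in MYOD effect in differentiation medium encode muscle proteins. TNNT3 stood at 0.419 ± 0.101 CPM in EMPTY GM and 0.451 ± 0.0156 in MYOD GM, against 0.175 ± 0.0356 and 599.6 ± 3.46 in differentiation medium, a difference of log2 effects of 11.62 ± 0.45, adjusted p = 9.3e-05. CKM gave 10.99 ± 0.62, adjusted p = 4.2e-04, the calcium channel subunit gene CACNG1 11.84 ± 1.21, adjusted p = 0.0047, and the light chain gene MYL1 11.32 ± 1.10, adjusted p = 0.0038. The heavy chain genes MYH8 and MYH2 gave 11.41 ± 0.94 and 10.15 ± 1.26. CACNA1S and CASQ2 completed these 8, with 2 and 3 reads in EMPTY DM, so that their fitted differences depend on the prior count. For MYOG the effect was higher in differentiation medium by 7.78 ± 0.41, adjusted p = 2.4e-04 and for MEF2C by 4.0 ± 0.53, adjusted p = 0.015.

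Other genes had a lower MYOD effect in differentiation medium, by different routes. SOCS3, an inhibitor of cytokine signalling, stood at 85.9 ± 1.45 and 129 ± 36.3 CPM in EMPTY GM and MYOD GM, and at 469 ± 37.9 and 42.1 ± 7.10 CPM in EMPTY DM and MYOD DM (difference −4.07 ± 0.37, adjusted p = 0.0029). ITGB4, an integrin of epithelial adhesion, stood at 20.4 ± 5.58 CPM in MYOD GM and between 1.23 and 2.73 CPM on average in the other groups (−4.80 ± 0.60, adjusted p = 0.012). LYPD5 (−4.95 ± 0.64), ATP1B2 (−4.43 ± 0.60), SECTM1 (−4.35 ± 0.59), SLC17A7 (−4.27 ± 0.49), the prostacyclin synthase gene PTGIS (−3.85 ± 0.65) and PDZD7 (−3.78 ± 0.43) completed the 8 largest that met the naming rule with its minimum of 10 CPM. KLF2 was higher with MYOD in growth medium (1.29 ± 0.25) and lower in differentiation medium (−2.03 ± 0.25), a difference of −3.32 ± 0.35, adjusted p = 0.0054.

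By list, 28 of 39 sarcomere genes had a higher MYOD effect in differentiation medium (34 over the list alone), a call that held with an estimated correlation (camera adjusted p = 5.3e-141, and adjusted p = 0.018 with an estimated correlation). The number was 11 of 23 for calcium handling and junction genes (14 over the list alone; camera adjusted p = 3.6e-34, and adjusted p = 0.074 with an estimated correlation), with RYR1 at 5.82 ± 0.38. In the fusion list 3 of 23 were higher, among them NCAM1 (8.87 ± 0.90) and CAV3 (2.80 ± 0.52) (8 over the list alone; camera adjusted p = 4.9e-08, and adjusted p = 0.19 with an estimated correlation). CKM, ENO3 (3.58 ± 0.59) and FABP3 (3.60 ± 0.67) were higher in the energy list (7; camera adjusted p = 7.0e-12, and adjusted p = 0.10 with an estimated correlation), and the regulator list was called with MYOG and MEF2C (camera adjusted p = 1.3e-05, and adjusted p = 0.19 with an estimated correlation; the same genes over the list alone). Lower as lists were the matrix genes, with DCN (−2.45 ± 0.35), TGFBI (−2.68 ± 0.40) and MMP2 (−2.50 ± 0.39) lower and MFAP5 (5.24 ± 0.72) higher (16 and 3 over the list alone; camera adjusted p = 7.5e-08, and adjusted p = 0.27 with an estimated correlation). The mesenchymal factors were lower too, with HOXA5 called (−2.26 ± 0.32; 3 over the list alone; camera adjusted p = 0.0011, and adjusted p = 0.17 with an estimated correlation). The serum response list was lower with JUNB (−3.47 ± 0.39), KLF4 (−3.54 ± 0.52), IER2 (−2.24 ± 0.34) and KLF2 (7 lower and 4 higher over the list alone; camera adjusted p = 0.012, and adjusted p = 0.40 with an estimated correlation). That call ended without EMPTY DM library 2 (camera adjusted p = 0.18; over 13 alternatives it ran from 1.5e-04 to 0.18). The epithelial, endothelial and blood list was lower as a list, with no member passing in edgeR, 4 lower at an unadjusted p under 0.05 and 1 lower in DESeq2 (camera adjusted p = 0.045, and adjusted p = 0.23 with an estimated correlation). With a filter at 1 CPM its camera adjusted p = 0.050 and the call ended; over 13 alternatives it ran from 0.0081 to 0.050.

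The cell cycle progression list was not called for the difference (camera adjusted p = 0.054), but it passed, lower, in 7 of 13 alternatives, which ran from 2.2e-06 to 0.99. In lists that did not pass, ANKRD1 (4.10 ± 0.54) and CD36 (3.74 ± 0.45) had a higher effect in differentiation medium and BTG2 (−2.93 ± 0.50), ID2 (−1.85 ± 0.30), ICAM1 (−2.04 ± 0.33) and COL11A2 (−2.80 ± 0.50) a lower one.

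edgeR's test of the difference called 351 genes, 182 with a higher and 169 with a lower MYOD effect in differentiation medium. Which direction held more genes depended on the setting, with 168 higher and 243 lower by library size only, 510 and 670 by DESeq2, and 515 and 1005 with no filter on low counts. Of the 182, 180 were also called higher in differentiation medium, 77 higher and 5 lower in growth medium. Of the 169, 154 were called lower in differentiation medium, and 32 higher and 18 lower in growth medium; each of these effects enters the difference, so some sharing follows from the construction. The count was 60 and 99 without EMPTY DM library 1 or 2, 837 without EMPTY GM library 2, 50 and 102 without MYOD DM library 1 or 2, and 174 and 159 without MYOD GM library 1 or 2. It was 1157 and 2634 without the growth medium libraries numbered 1 or 2, 1180 with DESeq2 and 1520 with no filter on low counts.

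**Figure D3:**
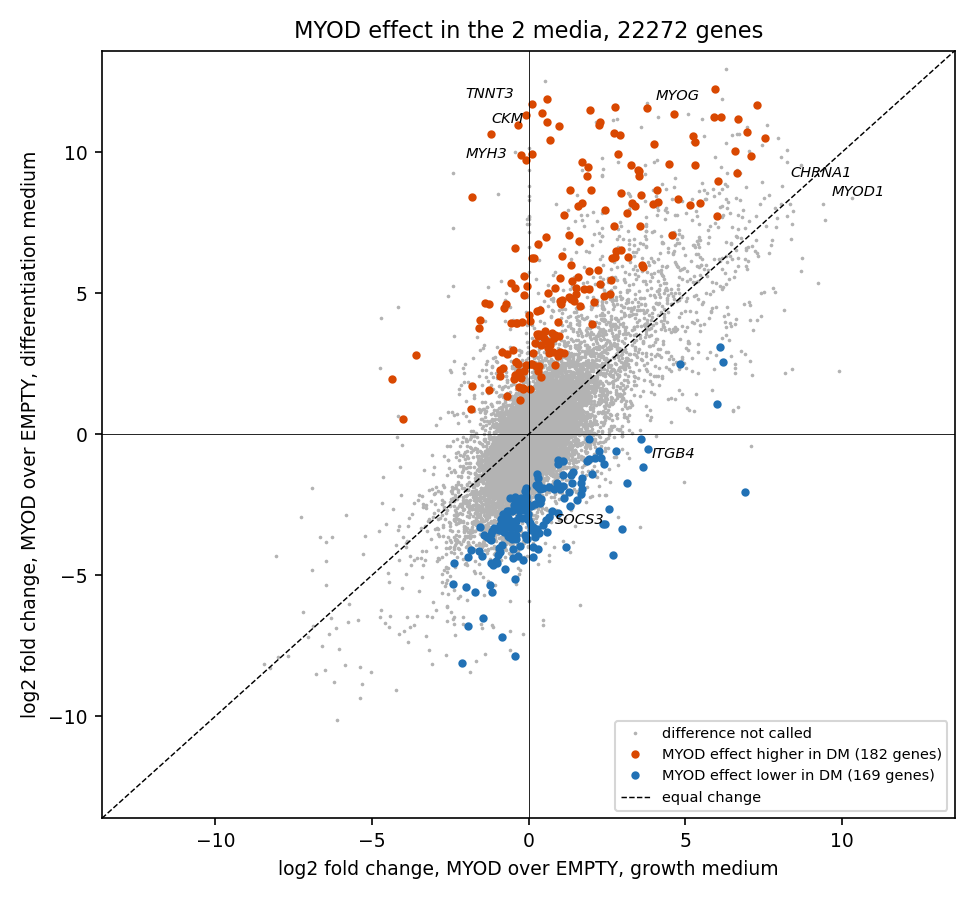
Each of 22272 genes by its log2 difference between MYOD and EMPTY cells in growth medium (x axis) and in differentiation medium (y axis); the dashed line marks equal change. Orange points are the 182 genes and blue points the 169 genes whose MYOD effect was higher or lower in differentiation medium by edgeR's test of the difference, and TNNT3, CKM and MYH3 lie near 0 on the x axis.

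When MYOD cells moved from growth to differentiation medium, 33 of 39 sarcomere and 15 of 23 sterol and fatty acid genes rose and 29 of 34 cell cycle genes fell. With an estimated correlation the sarcomere call held (adjusted p = 0.018), and those of the sterol and cell cycle lists did not (adjusted p = 0.11 and 0.21). MYL1 went from 0.0595 ± 0.0116 to 218 ± 30.0 CPM (mean ± SD, n = 2; log2 11.78 ± 0.46, adjusted p = 2.8e-05), and NEB, the nebulin gene, from 1.23 ± 0.689 to 882 ± 196 CPM (log2 9.46 ± 0.50, adjusted p = 6.6e-05). The embryonic heavy chain gene MYH3 (ENSG00000109063) went from 3.20 ± 1.13 to 2206 ± 245 CPM (log2 9.42 ± 0.39, adjusted p = 3.7e-05). TK1 (ENSG00000167900), the thymidine kinase of DNA synthesis, fell from 142 ± 58.5 to 9.58 ± 3.29 CPM (log2 −3.89 ± 0.59, adjusted p = 0.0069), and ID1 from 65.4 ± 26.8 to 2.58 ± 0.709 CPM (log2 −4.67 ± 0.60, adjusted p = 0.0036).

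The other large rises were in CACNG1 (11.12 ± 0.63), MYH8 (10.81 ± 0.53), TNNT3 (10.36 ± 0.32), CKM (10.19 ± 0.46), LMOD2 (9.53 ± 0.69) and CASQ2 (9.43 ± 0.60). Of 39 sarcomere genes 33 rose and 6 did not pass (37 over the list alone), a call that also held with an estimated correlation (camera adjusted p = 3.5e-129, and adjusted p = 0.018 with an estimated correlation). Rises numbered 16 of 23 for calcium handling (19 over the list alone; camera adjusted p = 5.4e-42, and adjusted p = 0.074 with an estimated correlation), as in RYR1 (5.15 ± 0.27) and HRC (8.48 ± 0.36). They numbered 13 of 23 for fusion (16; camera adjusted p = 2.4e-15, and adjusted p = 0.10 with an estimated correlation), as in NCAM1 (7.90 ± 0.57) and MYMK (6.07 ± 0.65). They numbered 7 of 20 for energy metabolism (15; camera adjusted p = 8.2e-12, and adjusted p = 0.11 with an estimated correlation), as in COX6A2 (6.26 ± 0.47) and FABP3 (4.16 ± 0.50). For regulators the number was 6 of 11 (9 higher and 1 lower over the list alone; camera adjusted p = 1.6e-09, and adjusted p = 0.11 with an estimated correlation), with MYOG (7.23 ± 0.27) and SIX4 (1.80 ± 0.26).

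Of 34 cell cycle progression genes 29 fell and 5 did not pass, and all 34 fell when adjusted over the list alone (camera adjusted p = 2.4e-26, and adjusted p = 0.21 with an estimated correlation). PLK1, a mitotic kinase gene, fell from 82.9 ± 12.6 to 9.75 ± 1.49 CPM, and HMGB2 (−2.42 ± 0.26) and CCNB2 (−2.99 ± 0.44) fell too. Of 23 sterol and fatty acid genes 15 rose (20 over the list alone; camera adjusted p = 2.5e-18, and adjusted p = 0.11 with an estimated correlation). Among them were the desaturase gene SCD (3.68 ± 0.34) and IDI1 (3.15 ± 0.35). KRT8 (−2.39 ± 0.24), KRT19 (−3.34 ± 0.45), EPCAM (−2.38 ± 0.47) and KRT18 (−1.70 ± 0.38) fell among 11 epithelial, endothelial and blood markers (7 lower and 1 higher over the list alone; camera adjusted p = 0.0014, and adjusted p = 0.11 with an estimated correlation). Besides ID1 and TK1, the 8 largest falls by the naming rule were in the protease inhibitor genes SPINT1 (−5.43 ± 0.42, adjusted p = 4.1e-04) and TFPI2 (−5.38 ± 0.86, adjusted p = 0.0084), CLIC3 (−4.56 ± 0.50), PSG4 (−4.43 ± 0.29), a member of a family of near-identical genes and so uncertain, ITGB4 (−4.05 ± 0.45) and NOTUM (−3.80 ± 0.38).

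The remaining lists did not pass for this comparison. ID2 (−2.59 ± 0.22), ID1 and ID3 fell and HEY1 (3.12 ± 0.38), JAG1 (2.79 ± 0.33), HES1, HEYL and NOTCH3 rose in the Notch and ID list (camera adjusted p = 0.39; 8 higher and 5 lower over the list alone). CDKN1A (1.25 ± 0.27), CDKN2B (2.40 ± 0.32), CCND2 (2.51 ± 0.47) and BTG2 rose and RBL1 (−1.32 ± 0.27) and CDKN2C fell among exit genes (camera adjusted p = 0.27; 7 and 4). Matrix genes included rises in MFAP5 (4.0 ± 0.50), VCAN and PDGFRB and falls in TGFBI (−1.92 ± 0.29), MMP2 (−1.62 ± 0.28), FBLN5 (−1.71 ± 0.35), FBLN2 and TIMP3 (camera adjusted p = 0.55; 6 and 8). HMOX1 (−1.96 ± 0.32) and NQO1 (−1.68 ± 0.34) fell among stress genes (camera adjusted p = 0.078; 3 lower over the list alone). DUSP4 (2.89 ± 0.32), DUSP6 (2.57 ± 0.30) and EGR2 (4.52 ± 0.59) were among 6 serum response genes that rose, with KLF2 (−1.74 ± 0.25) and IER2 lower (camera adjusted p = 0.12; 7 and 3). HES1, HEYL, NOTCH3, ID3, BTG2, CDKN2C, VCAN, PDGFRB, FBLN2, TIMP3 and IER2 were chosen after their values were seen.

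Among the mesenchymal factors PRRX1 (1.34 ± 0.35) rose and HOXA5 (−1.32 ± 0.23), OSR1 (−1.56 ± 0.38) and FOSL1 (−1.82 ± 0.37) fell (camera adjusted p = 0.078; 3 and 7). TGFB2 (1.41 ± 0.33) and ANKRD1 (2.19 ± 0.38) rose and CNN1 (−2.40 ± 0.47) and CCN1 (−1.13 ± 0.24) fell among myofibroblast genes (camera adjusted p = 0.99; 2 and 3). HDAC9 (2.25 ± 0.54) rose and EZH2 (−1.09 ± 0.25), LMNB1 (−1.58 ± 0.32), SMARCD2 (−1.37 ± 0.22) and SMARCD1 fell among chromatin genes, also over the list alone (camera adjusted p = 0.92). IRF7 (−1.81 ± 0.44) and ISG20 (−2.37 ± 0.36) fell in the interferon list, while OAS1, with 3 reads in MYOD GM, rose by a factor of 16.6 (95% counting interval 5.35 to 83.3) and CXCL10 by 33.2 (95% counting interval 5.54 to 1351) (camera adjusted p = 0.95; 3 and 3). CCL2 (2.23 ± 0.41) and VCAM1 (3.66 ± 0.54) rose and ICAM1 (−1.35 ± 0.24) fell in the inflammatory list (camera adjusted p = 0.65; 5 and 4). SMARCD1 was chosen after its values were seen.

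edgeR called 2403 genes for this move, 1194 higher and 1209 lower, of which 1137 and 1136 changed at least 2-fold; with library size as the only scaling the split was 1041 and 1590. The count was 1592 and 1594 without EMPTY DM library 1 or 2, 4922 and 4984 without EMPTY GM library 1 or 2, 418 and 631 without MYOD DM library 1 or 2, and 863 without MYOD GM library 2. It was 10519 and 4650 without the growth medium libraries numbered 1 or 2, and 4897 with no filter on low counts. The long minus small gene value described for each library, up to 0.35 in MYOD GM and at least 0.63 in MYOD DM, moved in the direction of this comparison.

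In EMPTY cells 4 of 34 matrix, 9 of 23 sterol and 5 of 25 serum response genes rose on the same move, and 7 of 34 cell cycle genes fell. These 4 lists were called by camera, and none held with an estimated correlation (adjusted p = 0.28, 0.15, 0.16 and 0.20). Their median log2 changes were 0.92, 1.47, 1.21 and −1.53. On the same move the median was 0.82 over genes with a long coding sequence and −0.97 over genes for small proteins. Whether transcript length enters the list changes was not tested. BTG2, an antiproliferative gene, rose from 16.5 ± 6.47 to 326 ± 37.8 CPM (mean ± SD, n = 2; log2 4.30 ± 0.39, adjusted p = 0.011), and the hyaluronan-degrading CEMIP gene rose by 4.41 ± 0.70, adjusted p = 0.032 with a wide spread in differentiation medium (582 ± 435 CPM). DCN rose from 359 ± 29.1 to 1568 ± 55.6 CPM (log2 2.13 ± 0.25, adjusted p = 0.020). MMP1, the interstitial collagenase gene, fell from 29.3 ± 6.26 to 1.66 ± 0.0797 CPM (log2 −4.14 ± 0.48, adjusted p = 0.019) as did CDC20, a gene of mitotic exit (log2 −2.83 ± 0.46, adjusted p = 0.033).

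Other large rises were in DEPP1 (3.87 ± 0.35), MTUS1 (3.85 ± 0.39), COL14A1 (3.81 ± 0.36), the mechanosensitive channel gene PIEZO2 (3.79 ± 0.44), and the complement genes C4A (4.02 ± 0.36) and C4B (4.22 ± 0.39), near-identical copies whose separate values are uncertain. Other large falls were in NPAS1 (−3.87 ± 0.57), TK1 (−3.00 ± 0.57), SPHK1 (−2.74 ± 0.45), the securin gene PTTG1 (−2.72 ± 0.49) and SPC24 (−2.70 ± 0.52).

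Of 34 cell cycle progression genes 7 fell and 27 did not pass, and 33 fell over the list alone (camera adjusted p = 5.3e-26, and adjusted p = 0.20 with an estimated correlation); PLK1 (−2.42 ± 0.32), MCM5 (−1.90 ± 0.33) and MYBL2 (−2.59 ± 0.47) were among them. Of 34 matrix genes DCN, LUM (1.97 ± 0.32), PDGFRA (2.01 ± 0.37) and COL3A1 (1.63 ± 0.32) rose (19 over the list alone; camera adjusted p = 5.3e-08, and adjusted p = 0.28 with an estimated correlation). Of 23 sterol genes 9 rose (18; camera adjusted p = 1.6e-16, and adjusted p = 0.15 with an estimated correlation), such as FADS2 at 2.55 ± 0.32. JUNB (2.83 ± 0.29), KLF4 (3.36 ± 0.38), KLF2 (1.58 ± 0.25), EGR2 (3.66 ± 0.63) and IER2 rose among 25 serum response genes (15 higher and 2 lower over the list alone; camera adjusted p = 5.5e-08, and adjusted p = 0.16 with an estimated correlation). BTG2 and CCND2 (2.78 ± 0.48) rose among exit genes (7 and 2; camera adjusted p = 7.9e-04, and adjusted p = 0.11 with an estimated correlation). VCAM1 (3.74 ± 0.54), IL6 (2.63 ± 0.42), CXCL2 and CXCL6 rose and MMP1 and IL11 (−2.68 ± 0.46) fell in the inflammatory list (10 and 3; camera adjusted p = 0.013, and adjusted p = 0.28 with an estimated correlation), a list test with 13 alternatives from 7.8e-05 to 0.22. Its call ended without the growth medium libraries numbered 1 (adjusted p = 0.22) or 2 (adjusted p = 0.085). IER2, CXCL2 and CXCL6 were chosen after their values were seen.

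Of the muscle lists in EMPTY cells, SGCD (2.75 ± 0.22) rose and CDH2 (−1.43 ± 0.29) fell in the fusion list (camera adjusted p = 0.26). No regulator, sarcomere, calcium or energy gene passed in edgeR's fit of all libraries. At an unadjusted p under 0.05 those 4 lists held 4, 3, 3 and 1 higher genes and 0, 8, 1 and 4 lower ones, and DESeq2 called 2, 1, 0 and 0 higher and 0, 4, 0 and 1 lower. As lists, the sarcomere genes passed, lower, in 4 of 13 alternatives and the regulators, higher, in 1. MYOD1 itself differed by −0.17 ± 0.79, adjusted p = 0.90. Single members of other lists passed, with JAG1 (1.63 ± 0.31) and IFIT2 (2.05 ± 0.42) higher and FOSL1 (−2.48 ± 0.37), ANKRD1 (−1.91 ± 0.39), LMNB1 (−1.58 ± 0.32), NQO1 (−1.98 ± 0.34) and KRT8 (−1.78 ± 0.24) lower.

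edgeR called 526 genes for the move in EMPTY cells, 350 higher and 176 lower, of which 350 and 171 changed at least 2-fold; 6034 had an unadjusted p under 0.05. The count fell to 0 without EMPTY DM library 1 or 2 (2560 and 3752 at an unadjusted p under 0.05), and was 41 and 42 without MYOD DM library 1 or 2, 345 and 6377 without EMPTY GM library 2 or 1, and 10885 and 3386 without the growth medium libraries numbered 1 or 2. The count was also 2836 with DESeq2, 4313 with no filter on low counts, and 25 in a fit of the EMPTY libraries alone. By DESeq2 1413 were higher and 1423 lower. The excess of rises was smaller without EMPTY GM library 1 (3228 and 3149) and without the growth medium libraries numbered 2 (1737 and 1649). The long minus small gene value also separated EMPTY GM (−0.26 and −1.62) from EMPTY DM (1.04 and 0.69). On the move to differentiation medium 214 genes were called the same way in both kinds of cell and 19 opposite ways. Independent lists would share 28.3 the same way, which is not the number without a shared change: the growth medium pairs deviated together, and the long minus small gene value was higher in differentiation medium in both kinds of cell.

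**Figure D4:**
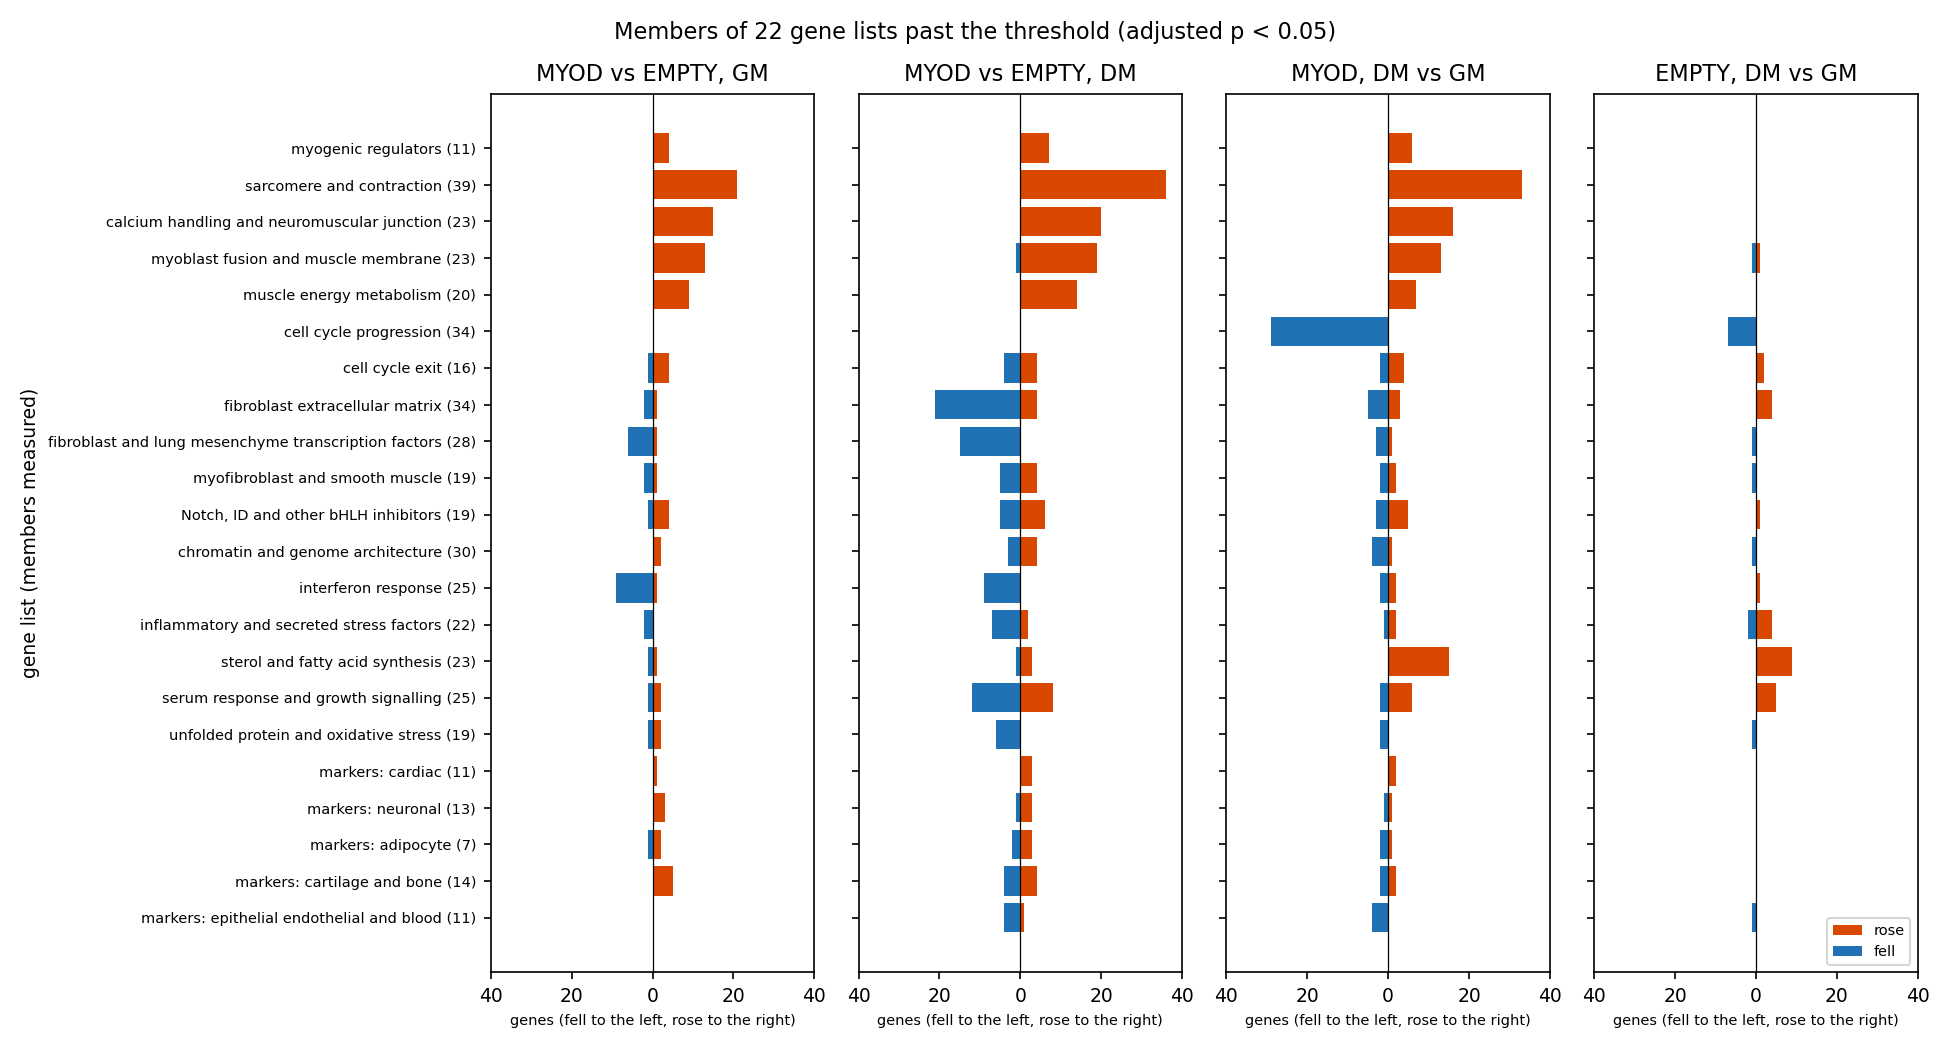
For 22 gene lists and 4 comparisons, the number of measured members that rose and that fell in edgeR's test. In differentiation medium 36 of 39 sarcomere genes rose with MYOD and 21 of 34 matrix genes fell, and on the move of MYOD cells to differentiation medium 29 of 34 cell cycle progression genes fell.

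The authors' deposited table for MYOD in growth medium called 1305 genes at an adjusted p under 0.05, 1033 higher and 272 lower, and 1236 of these were called in the same direction by edgeR here. The authors' deposited table for differentiation medium called 9784 (4818 higher, 4966 lower), of which 5668 were shared, and their deposited table for the move of MYOD cells called 4105 (2058 and 2047), of which 2249 were shared. No gene called in both was called in opposite directions. Log2 values from the authors' deposited tables and from the fit here correlated across genes with r of 0.916, 0.981 and 0.963.

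The MYOD chromatin immunoprecipitation regions, deposited as common to growth and differentiation medium, numbered 27777 on 23 chromosomes of hg19 and covered 12.8 Mb. Their median width was 391 bp and their widths ran from 236 to 3136 bp. The authors' score per region had a median of 0.568 and reached 2.77 at chromosome 7, positions 75114850 to 75115105. The next by score were chromosome 1, 169075809 to 169076075 (2.77), chromosome 1, 229544559 to 229544799 (2.73), chromosome 1, 155939145 to 155939391 (2.72) and chromosome 17, 46647876 to 46648149 (2.68). What the score measures is not given in the sources used here, so the order by score is not to be read as one of binding strength. Chromosomes 1, 17 and 2 held 2720, 1966 and 1917 regions. Which genes the regions lie near was not analysed here.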

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

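All of the tests of explanations given here were chosen after the results they bear on had been seen, and the comparisons of the MYOD effect between media were planned.

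The MYOD effect differed between the media by edgeR's test of the difference for 351 genes, 182 with a higher and 169 with a lower effect in differentiation medium, and for 9 gene lists by camera. Among genes with at least 10 CPM in their highest group that met the naming rule, the largest higher effects were in the muscle genes CACNG1 (11.84 ± 1.21, log2), TNNT3 (11.62 ± 0.45), MYH8 (11.41 ± 0.94), CACNA1S (11.33 ± 1.49), MYL1 (11.32 ± 1.10), CKM (10.99 ± 0.62), CASQ2 (10.48 ± 1.49) and MYH2 (10.15 ± 1.26). The largest lower effects by that rule were in LYPD5 (−4.95 ± 0.64), ITGB4 (−4.80 ± 0.60), ATP1B2 (−4.43 ± 0.60), SECTM1 (−4.35 ± 0.59), SLC17A7 (−4.27 ± 0.49), SOCS3 (−4.07 ± 0.37), PTGIS (−3.85 ± 0.65) and PDZD7 (−3.78 ± 0.43). The count of genes was 60 and 99 without EMPTY DM library 1 or 2, 50 and 102 without MYOD DM library 1 or 2, 174 and 159 without MYOD GM library 1 or 2, and 837 without EMPTY GM library 2. CACNA1S and CASQ2 had 2 and 3 reads in EMPTY DM, so their fitted differences depend on the prior count. Only the list of sarcomere genes kept its call with an estimated correlation (adjusted p = 0.018).

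Reads in no annotated gene made up 12.4% and 12.5% of the MYOD DM files, above the range of the other 6 files, which reached 10.6% in EMPTY DM. In the authors' deposited table that class of reads was higher in MYOD DM than in EMPTY DM by 0.44 (log2, adjusted p = 0.0127).

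The growth medium libraries numbered 1 and 2 stood apart in both vectors. Depth is argued against, because the deviations of both pairs correlated across genes (r = 0.699) although library 1 was the shallower in EMPTY GM and the deeper in MYOD GM. The long minus small gene value of MYOD GM library 1 lay 81.3% of the way, on the log2 scale, from library 2 to the MYOD DM mean. If a mixture with differentiated cells made this gap, sarcomere genes would stand well higher in library 1. But the excess of 33 sarcomere genes in library 1 had a median of 0.111% of their differentiation medium level (IQR −0.116 to 0.991). Of the 33, 6 were at least 2-fold higher. The EMPTY GM pair was not tested for a mixture. A difference in cell cycle state stays open: the median gap of the cell cycle list was at least 0.635 in the differentiation medium pairs, but its members spread too widely to set this apart from the growth medium pairs. Open too is a different recovery of short and long transcripts, which may account for the pattern: the median change from library 2 to library 1 over the long genes, minus that over the small ones, was 1.62 and 1.64 (log2) in the growth medium pairs and 0.22 in both differentiation medium pairs. In EMPTY GM and MYOD GM the median change was −0.90 and −0.88 over ribosomal protein genes. Over genes of respiratory chain subunits it was −0.84 and −0.72. Transcript length was therefore not separated from a change in the expression of such gene families. A difference in the state of the cultures or in the sequencing run was not tested.

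Nuclear copies of mitochondrial genes took more reads in MYOD DM. They held 4.78% and 5.52% of reads on genes in MYOD DM and between 3.13% and 3.78% in the other 6 libraries, and all 30 tested copies were higher with MYOD in differentiation medium, 5 of them called. The choice among 3 scalings does not account for this, since their median log2 difference was at least 0.611 under each. These scalings moved the median of all genes only between −0.151 and 0.049, so a larger error of scaling was not tested. Transcripts of the mitochondrial genome counted on nuclear copies may account for the pattern: the 37 mitochondrial genes themselves had 0 reads, and 28 copies of 10 mitochondrial genes moved by source gene more than chance gives (permutation p = 0.00339, 100000 permutations; 4.9e-04 for the move of MYOD cells, and 0.0573, 0.643 and 0.662 in the other contrasts). A first version of that test read an incomplete set of copies and was replaced; whether mitochondrial transcripts were truly more abundant in these cells stays open.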

How the results depend on the processing

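The block within each medium and the fits without the growth medium libraries of a number were chosen after seeing the data. Named genes had been chosen for a like direction in their libraries, so that their direction with libraries left out follows from the choice and shows no stability. Of their 6320 recomputed values with a test, on 354 results, 700 no longer passed; 171 results passed under every such setting. With only the libraries numbered 1 or only those numbered 2, where no test was possible, 111 and 115 of the 354 values moved by more than the SE. DESeq2, no filter and the replicate block lost 0 of 354, a fit of only the libraries compared 71 of 308, and leaving out MYOD DM library 1 the most, 138.

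For MYOD in growth medium (1855 genes) the count was 3026 with no low-count filter, 558 with only the libraries compared, 5273 with the block within each medium, 3586 without growth medium libraries numbered 2, and 894 to 2446 over single libraries left out (894 without MYOD GM library 1, 1182 and 1189 without MYOD DM library 1 or 2). In differentiation medium (5898) it was 11033 with only the libraries compared, 11107 with that block, 11302 and 11427 without the growth medium libraries numbered 1 or 2, and 2391 to 7893 over libraries left out (2795 and 3287 without EMPTY DM library 1 or 2, 2391 and 3214 without MYOD DM library 1 or 2). For MYOD cells moved to differentiation medium (2403) it was 4897 with no filter, 4342 with that block, 10519 and 4650 without growth medium numbers 1 or 2, and 418 to 4984 over libraries left out (1592 and 1594 without EMPTY DM library 1 or 2, 4922 and 4984 without EMPTY GM library 1 or 2, 418 and 631 without MYOD DM library 1 or 2, 863 without MYOD GM library 2).

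For EMPTY cells (526) the count was 2836 with DESeq2, 4313 with no filter, 25 with only the libraries compared, 3576 with the block within each medium, 10885 and 3386 without growth medium numbers 1 or 2, and 0 to 6377 over libraries left out. The edgeR count was 0 without EMPTY DM library 1 or 2 (2560 and 3752 at an unadjusted p under 0.05; DESeq2 was not run without single libraries). It was 6377 and 345 without EMPTY GM library 1 or 2, and 41 and 42 without MYOD DM library 1 or 2. For the difference of effects (351) it was 1180 with DESeq2, 1520 with no filter, 3651 with the block within each medium, 1157 and 2634 without growth medium numbers 1 or 2, and 50 to 837 over libraries left out (60 and 99 without EMPTY DM library 1 or 2, 837 without EMPTY GM library 2, 50 and 102 without MYOD DM library 1 or 2, 174 and 159 without MYOD GM library 1 or 2). The overlap of both MYOD effects (1501) was 4015 with that block, 2668 without growth medium number 2, and 803 to 1810 over libraries left out (939 and 923 without EMPTY DM library 1 or 2, 859 and 937 without MYOD DM library 1 or 2, 803 without MYOD GM library 1). Fewer samples or genes enter some of these fits. All groups also share an estimate of the spread, although the spread per library was 0.65 and 0.54 in the growth medium pairs and 0.31 in both differentiation medium pairs. By the spread alone, the SEs and adjusted p within growth medium may be too small, and those within differentiation medium too large. But the deviations of EMPTY GM and MYOD GM by replicate number correlated at 0.70 across genes, and a shared part cancels in the MYOD effect. Whether the SEs of the MYOD effect in growth medium are too small or too large is therefore not settled. Otherwise the cause was not tested.

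With the replicate number as a block the counts were 2311, 6871, 3560, 2418 and 656 for these 5 comparisons, and the overlap 1857. For the difference of effects the split was 275 higher and 381 lower, and 1429 and 2222 with the block within each medium, against 182 and 169 without a block. The labels give no pairing, and the numbers were not taken to pair the libraries, although those of growth medium deviated together: deviations from the group means correlated at 0.70 between EMPTY GM and MYOD GM and at −0.02 to 0.15 between other groups. With an estimated correlation 3 of 39 list calls held, and calls were lost also where the estimate was under the preset value. Under other settings calls were lost for inflammatory genes in EMPTY cells (adjusted p = 0.22 and 0.085 without growth medium numbers 1 or 2; 7.8e-05 to 0.22 over 13 alternatives), and in the difference of effects serum response genes (0.18 without EMPTY DM library 2, 0.064 with the block within each medium; 1.5e-04 to 0.18) and epithelial, endothelial and blood markers (0.050 at the 1 CPM filter; 0.0081 to 0.050). Of 71 list tests not called, 26 passed under at least 1 alternative. Those that did so most often were, lower with MYOD in differentiation medium, stress (9 of 13; 0.026 to 0.076), serum response (7; 0.0020 to 0.16) and inflammatory genes (4; 0.0045 to 0.10). Others were Notch and ID genes with MYOD in growth medium (5; 0.0059 to 0.26), and for the difference of effects cell cycle progression (7; 2.2e-06 to 0.99; 0.0069 with the replicate block, 3.4e-05 within each medium) and sterol genes (4; 4.2e-04 to 0.39). Sarcomere genes in EMPTY cells passed, lower, in 4 (0.025 to 0.27). With library size as the only scaling the median of all genes moved to −0.15 for MYOD in differentiation medium and to −0.16 for the difference of effects, against −0.01 and −0.03, and no called list's median changed sign. A lone library of a group is assumed to vary like the other groups. Depth limits genes with few reads in a group. The gene neighbourhood and E-box alternatives of the MYOD regions were not run.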

Other observations

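The comparisons of the genes described here were chosen after seeing the data.

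For 20 genes the MYOD effect was called in opposite directions in the media and also differed by edgeR's test of the difference, 17 of them higher with MYOD in growth medium and lower in differentiation medium. TACR1, the neurokinin 1 receptor gene, changed by 2.56 ± 0.35 (log2 ± SE) in growth medium and by −2.63 ± 0.36 in differentiation medium. DEPP1, a target of FOXO transcription factors, changed by 1.70 ± 0.33 and −1.93 ± 0.33. FAXDC2 changed by 1.86 ± 0.28 and −0.94 ± 0.27, and the kinase gene RPS6KA2 by 1.10 ± 0.24 and −0.95 ± 0.24. The 3 genes that went the reverse way were ENDOD1 (−1.26 ± 0.21 and 1.56 ± 0.21) and, with too few reads in MYOD GM for a fold to be given, the heparan sulfate sulfotransferase gene HS6ST2 and STARD13-AS, an antisense gene whose counts are uncertain because the strand setting is not known. All of these genes were chosen after their values were seen.

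Cell cycle progression genes were lower in library 1 than in library 2 of all 4 groups. The median log2 difference over the 34 genes was −0.44 in EMPTY GM, −0.47 in MYOD GM, −0.77 in EMPTY DM and −0.63 in MYOD DM. Replicate numbers have no stated meaning in the labels, and the difference was not tested.

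Across genes, the difference between the libraries of MYOD GM correlated with the change of EMPTY cells on the move to differentiation medium (r = 0.53), and that between the libraries of EMPTY GM with the change of MYOD cells (r = 0.36). Genes are not independent replicates, and those values come from different libraries.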
